A study of Homo sapiens with 36 samples.

How the data were processed

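Per the labels, BE(2)-C cells were transfected with siRNA for 24 hours, RNA was extracted and libraries were prepared by m6ACE, with input libraries in each group. The labels give one growth and treatment text, written for BE(2)-C, for all samples, and describe HEK293T as neuroblastoma. HEK293T is named as the cell line there, and its own treatment is not given in the sources used here. The table without ATRA is named for DMSO, whereas the labels say only that ATRA was absent.

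The authors deposited a table per context with a ratio, the relative methylation level (RML), for each m6ACE library. The formula and the scaling between libraries are not given in the sources used here. The deposited tables also hold each group's mean RML as a ratio, a log2 fold change of siScram over siPcif1, and p-values, per the file headers. The deposited mean equals the mean of the 3 replicates within rounding, and the deposited p-value of the fold change was checked to follow a one-sided test on the ratios. Per the submitters' processing notes the tools were bcl2fastq 2.20, cutadapt 3.7, Bowtie2, STAR and DESeq2 with the hg38 build, with roles and order not given. In every row the smaller of the 2 DESeq2 p-values that the authors deposited was at most 0.05, so the tables list only sites called in at least 1 group. No library has 0 as a value. Input libraries have no column of their own, and the number of per-sample columns left unused was 0. Depth per site is unknown, so no counting interval is given.

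Values were analysed as log2(RML + pseudocount), with the 5th percentile of each table as pseudocount (0.502, 0.857 and 0.298 for BE(2)-C without ATRA, with ATRA and HEK293T). Fold changes on this scale understate the change of low sites. All changes are siPcif1 minus siScram, which is opposite in sign to the deposited column. The planned filter, a value above 0 in at least 3 libraries, removed 0 sites. limma 3.58.1 in R 4.3.3 fitted each context separately with lmFit and eBayes with a variance trend, and p-values were adjusted by Benjamini-Hochberg at 0.05. For BE(2)-C without ATRA the fit had 91420 total degrees of freedom, so the variance was almost wholly shared between sites and calls are optimistic.

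Sites the authors annotated as 5'UTR formed the 5' class, and coding and 3'UTR sites the internal class. DRACH and BCA were read from the 5-base motif around the adenosine. Start sites below are 5'UTR sites without a DRACH motif, at any distance from the gene start. Class differences were medians per library, compared by exact two-sided permutation over the 20 arrangements of 6 libraries. Differences between contexts permuted context labels within siScram and within siPcif1, with 400 relabelings. Distances used the outermost gene bounds of the RefSeq table of GRCh38. Symbols matched it for 98.7% to 99% of annotated sites. Gene lists were tested with fry and camera, and members were counted over all sites and over the list alone. Named genes followed a rule fixed before the data were examined. Per context it took the 10 largest decreases and 5 largest increases among called sites above the median level whose libraries did not overlap. It added PCIF1, PCF11, METTL3, FTO and MYCN, and the 2 members with the smallest p of each list with at least 3 genes, up to 30 genes. Each gene named by this rule was shown by its lead site, that with the smallest adjusted p. Ties went to the larger absolute change.

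Some steps were added after the data had been seen. These were level-matched and DRACH-based comparison sites, centring on internal DRACH sites, values without a pseudocount, sites called in siPcif1, the deposited p-values doubled to match a two-sided test, the gene-level 5'UTR test and the start-site versions of the gene lists. The gene-level test was added because the planned site test called 0 sites in HEK293T. Level matching used 10 bins of mean level over the libraries of both groups, with at least 20 internal sites each. Settings listed before the data were examined were another centring, a stricter filter, pseudocounts at the 1st percentile and at the median, the replicate number as a block, no variance trend, the deposited p-values and leaving out each library.

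The code was tested on simulated data. Of 100 sites lowered by 2 on the log2 scale, limma recovered 77% in BE(2)-C without ATRA, 65% with ATRA and 29% in HEK293T, with 5, 3 and 0 false calls. Of 100 genes lowered by 2, the gene-level test recovered 59% in HEK293T with 4 false calls, and 6% of 100 genes lowered by 1. Noise was drawn independently for each site or gene, without differences shared across a library. The false calls therefore say nothing about errors that such shared differences cause in the real tables.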

Results

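Methylated adenosines were mapped by m6ACE, an antibody crosslinking and exonuclease method that places N6-methylated adenosines at single-base resolution. It detects both internal m6A, written by METTL3 mostly in the DRACH sequence context, and m6Am, the methylated adenosine next to the mRNA cap that is written by PCIF1. Cells received siRNA against PCIF1 (siPcif1) or a scrambled control (siScram). The 36 samples form 12 groups of 3, with 18 m6ACE libraries and 18 input libraries in 3 contexts. The contexts were BE(2)-C, a human neuroblastoma line, without and with all-trans retinoic acid (ATRA, a differentiating agent, 10 uM for 4 days), and HEK293T, a human embryonic kidney line. Each context came as its own table of relative methylation levels (RML), a ratio for each m6ACE library whose formula is not given in the sources used here. The read depth behind each ratio is unknown. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

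The table for BE(2)-C without ATRA listed 22855 sites, that for BE(2)-C with ATRA 21031 sites and that for HEK293T 57011 sites. In HEK293T 12374 sites lay in 5'UTRs (21.7%), 26209 in coding sequence and 13538 in 3'UTRs. Of the BE(2)-C sites, 2147 without ATRA (9.39%) and 2104 with ATRA (10%) lay in 5'UTRs. A DRACH motif was present at 60.3% of coding and 3'UTR sites in HEK293T, at 22.5% in BE(2)-C without ATRA and at 24.8% with ATRA. In 5'UTRs the adenosine followed a cytosine in the context BCA at 54.7%, 53.8% and 56.5% of sites, in the same order. PCIF1 itself was not checkable as a knockdown target, because RML is not an expression level. Its site with the smallest adjusted p, in the 3'UTR, had RML of 1.06 ± 0.42 (SD, n = 3) in siScram and 1.24 ± 0.22 in siPcif1 in HEK293T.

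The first question was whether PCIF1 depletion lowered methylation at transcript 5' ends relative to internal sites, which was clearest in HEK293T. There the median level of 5'UTR sites exceeded that of coding and 3'UTR sites by 1.09 ± 0.015 on the log2 scale (SD, n = 3) in siScram and by 0.36 ± 0.07 in siPcif1. The difference fell by 0.73, or 1.65-fold, and the 3 siPcif1 libraries all lay below the 3 siScram libraries. The exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Over single sites, the median change was -0.65 in 5'UTRs and 0.01 at coding and 3'UTR sites. Camera, a set test, gave p = 3.45e-33 for the 12374 5'UTR sites with its preset correlation and p = 0.00497 with an estimated correlation.

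**Figure D1:**
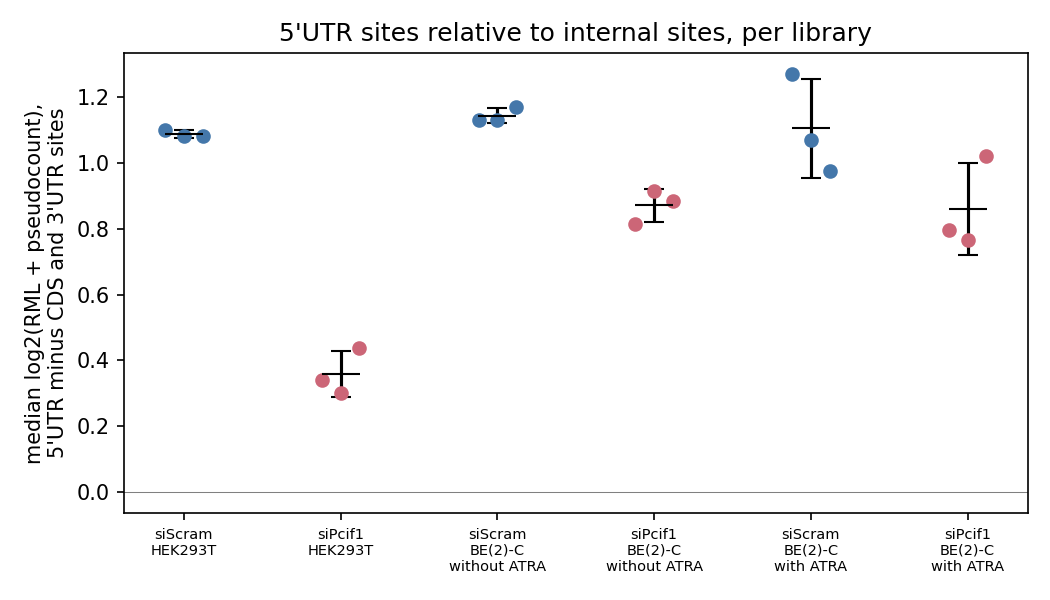
Difference of median log2(RML + pseudocount) between 5'UTR sites and coding plus 3'UTR sites, with a point for each library and the mean and SD of 3 libraries as bars, for siScram and siPcif1 in each context. In HEK293T the mean was 1.09 in siScram and 0.36 in siPcif1, and in BE(2)-C with ATRA the libraries of the groups overlapped.

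The HEK293T change was largest near gene starts. Relative to internal DRACH sites, the 11302 5'UTR sites without a DRACH motif fell by 0.77 and the 6770 5'UTR sites in the BCA context by 0.83. The fall was not limited to BCA. Non-DRACH 5'UTR sites fell by 0.78 after a T (2111 sites), by 0.72 after a G (1751 sites) and by 0.44 after an A (212 sites). The 1072 5'UTR sites with a DRACH motif fell by 0.11. Over sites of any region, non-DRACH sites changed by -0.75 upstream of the RefSeq gene start (2114 sites) and by -0.77 at it (1751 sites). Those 1 to 10 nt downstream changed by -0.82 and those at 11 to 50 nt by -0.81, so the fall did not peak at the start itself. Those at 51 to 100 nt changed by -0.53, those at 101 to 500 nt by -0.36 and those beyond by -0.05. DRACH sites changed by -0.91 at 1 to 10 nt (43 sites), -0.66 at 11 to 50 nt (72 sites), -0.24 at 51 to 100 nt (57 sites) and -0.002 at 101 to 500 nt (736 sites). At 51 to 100 nt and at 101 to 500 nt they thus fell less than non-DRACH sites at the same distance, whereas nearer the start both fell. These bins hold sites of any region, so the part of position in the small change of DRACH 5'UTR sites as a whole stays open. The libraries of the groups did not overlap at 36.1% of non-DRACH 5'UTR sites in the direction of lower siPcif1 and at 0.54% in the other, where chance gives 5% each way. Among internal DRACH sites these shares were 5.29% and 6.33%.

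**Figure D2:**
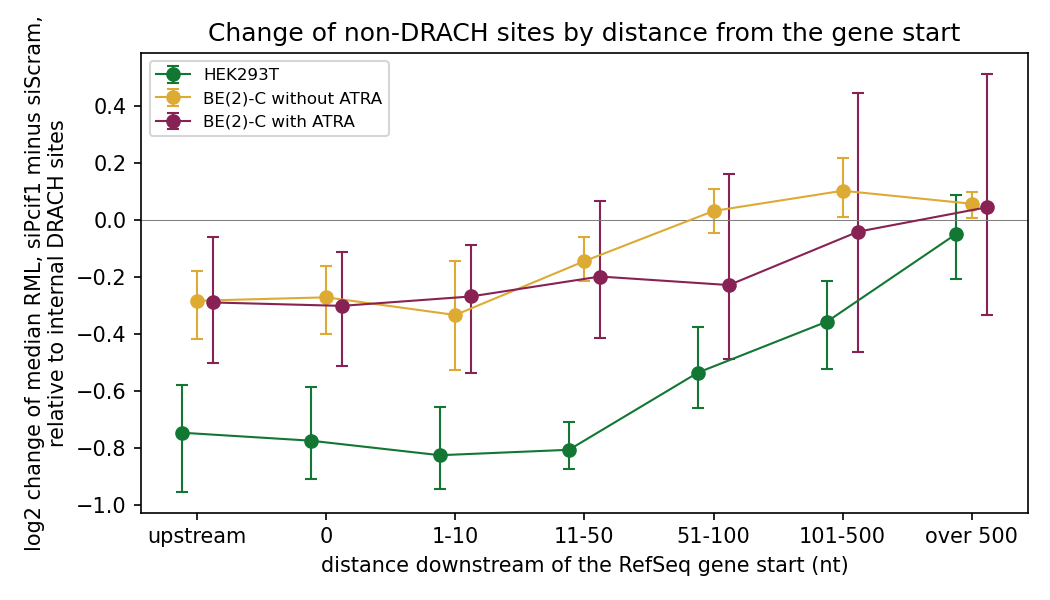
Change of the median log2 RML of sites without a DRACH motif (siPcif1 minus siScram, relative to internal DRACH sites) by distance in nt from the RefSeq gene start, with 1 line per context. Points are means and bars span the lowest and highest pair of a siPcif1 and a siScram library; in HEK293T the value was -0.81 at 11 to 50 nt and -0.05 beyond 500 nt.

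The same contrast was smaller in BE(2)-C. Without ATRA the 5'UTR excess was 1.14 ± 0.02 (SD, n = 3) in siScram and 0.87 ± 0.051 in siPcif1, a difference of -0.27 (exact permutation p = 0.1). With ATRA it was 1.1 ± 0.15 in siScram and 0.86 ± 0.14 in siPcif1, a difference of -0.24 (exact permutation p = 0.2), and the libraries of the groups overlapped. Camera with an estimated correlation gave p = 0.526 without ATRA and p = 0.187 with ATRA, against 5.33e-05 and 5.69e-18 with the preset correlation. With each library centred on its median, the estimated correlation gave p = 7.27e-05 without ATRA and p = 0.0307 with ATRA. Against internal sites of like level the difference was -0.06 without ATRA (exact permutation p = 0.3) and -0.22 with ATRA (exact permutation p = 0.1). The HEK293T shift differed by -0.45 from that of BE(2)-C without ATRA and by -0.48 from that with ATRA (exact permutation p = 0.1 and p = 0.055, both 0.15 after Benjamini-Hochberg adjustment over 3 pairs of contexts). Each contrast was formed within its own table, because the scaling of the tables is not given in the sources used here.

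Testing site by site, limma passed 0 of 57011 sites in HEK293T at an adjusted p of 0.05, with 5309 lower and 1588 higher at an unadjusted p of 0.05 (3917 and 2873 after each library was centred on its median). For the 12374 5'UTR sites alone, a class fixed before the data were examined, 279 sites were lower and 1 higher when adjusted over the list alone, and 0 in both directions after each library was centred on its median. In the authors' deposited table, whose p-values follow a one-sided test, 6042 sites were lower and 2515 higher at an unadjusted p of 0.05, and 2 were lower after Benjamini-Hochberg adjustment. With the p-values of the authors' deposited table doubled, to set them beside the two-sided limma test, the counts were 3475 and 1257, and 1 was lower after adjustment. The lead site of METTL3 among its 8 sites was in the 5'UTR, at position 21511329 of chromosome 14 (hg38). It had RML of 18.8 ± 13 (SD, n = 3) in siScram and 2.98 ± 1.4 in siPcif1 (limma adjusted p = 0.19). PCF11, a cleavage and termination factor, had its lead site at position 83157390 of chromosome 11, in the 5'UTR, with 2.39 ± 0.57 and 1.23 ± 0.45 (limma adjusted p = 0.38). Of 2 FTO sites, the lead site was in coding sequence and had 1.54 ± 0.36 and 1.27 ± 0.33 (limma adjusted p = 0.86).

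A test per gene was added after the site test had returned 0 sites. It averaged the non-DRACH 5'UTR sites of each gene relative to internal DRACH sites, which is called start-site RML below. Many of these sites need not lie at the transcript start. Of 12086 HEK293T 5'UTR sites of any motif with a known distance, 8559 lay within 100 nt of the RefSeq gene start. In BE(2)-C these numbers were 2112 and 1351 without ATRA and 2063 and 1293 with ATRA. Of 5069 HEK293T genes 92.3% had a negative change, with a median of -0.74, and the libraries of the groups separated downward in 41.1% and upward in 0.493% of genes, where chance gives 5% each way. limma called 217 genes lower and 0 higher at an adjusted p of 0.05 (1815 and 11 at an unadjusted p of 0.05). This count rested on the full set of libraries. It was 0 without siScram replicate 1, 2 or 3, 0 without siPcif1 replicate 2 or 3 and 2 without siPcif1 replicate 1. The count was also 0 without the variance trend and 0 with the replicate number as a block. For BE(2)-C, limma called 0 of 1240 genes without ATRA (136 lower and 24 higher at an unadjusted p of 0.05) and 0 of 1234 with ATRA (205 and 18).

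The genes with the largest decreases among those 217 included MED25, a Mediator subunit, DIS3L2, an exoribonuclease, DPM1, which makes dolichol-phosphate mannose, and SLC7A8, an amino acid transporter. The DPM1 site at position 50958532 of chromosome 20 had RML of 77.2 ± 39 (SD, n = 3) in siScram and 13.8 ± 2.4 in siPcif1, a log2 change of -2.37 ± 0.41 (SE; limma adjusted p = 0.04). FAM8A1 had 17 ± 1.6 and 2.71 ± 0.22 at position 17600352 of chromosome 6, a change of -2.53 ± 0.38 (limma adjusted p = 0.04). SBNO2 had the largest decrease, from 20.2 ± 7.4 to 2.26 ± 0.59, a change of -2.96 ± 0.47 (limma adjusted p = 0.04). Each of these genes had 1 non-DRACH 5'UTR site, so its value is that of a single site. The planned site test passed 0 HEK293T sites, with a smallest limma adjusted p of 0.157.

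**Figure D3:**
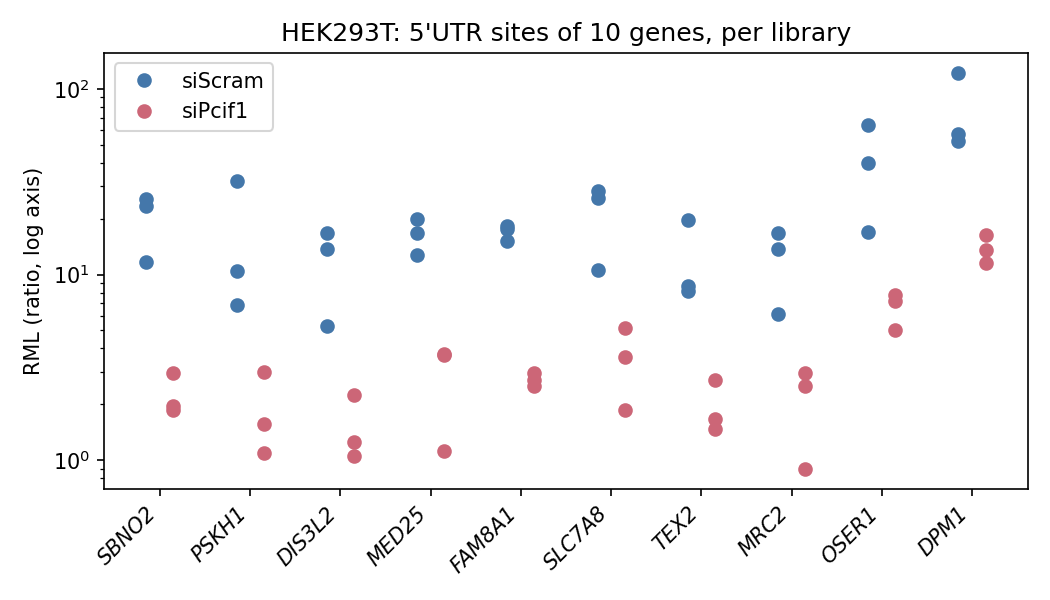
RML (ratio, log axis) of the non-DRACH 5'UTR site of 10 HEK293T genes, with 1 point per library for siScram and siPcif1. The genes were chosen for the largest decreases among genes whose libraries did not overlap, so their separation is built into the choice; SBNO2 averaged 20.2 in siScram and 2.26 in siPcif1.

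Most sites in BE(2)-C without ATRA were lower after siPcif1, at internal positions too. The median change over all sites was -0.43 on the log2 scale, with -0.64 in 5'UTRs, -0.41 at coding and 3'UTR sites and -0.47 at internal DRACH sites. limma called 843 sites lower and 5 higher, of which 184 lower and 2 higher were in 5'UTRs (330 and 2 adjusted over the list alone). With each library centred on its median the count was 0 in both directions, and 1 5'UTR site was lower adjusted over the list alone. At an unadjusted p of 0.05, 5985 sites were lower and 18 higher as deposited, against 1126 and 2921 after centring. The 82 sites on the mitochondrial chromosome, a class set after the data had been seen and low in RML, had a median change of 0.06 as deposited and of 0.55 after centring, when 80 were higher adjusted over that class alone. As deposited, the count over all sites was 12188 lower and 22 higher without siScram replicate 1, and it was 78, 62, 40, 160 and 84 lower without siScram replicate 2, siScram replicate 3, siPcif1 replicate 1, siPcif1 replicate 2 and siPcif1 replicate 3. Without the variance trend 1 site was lower.

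Relative to that overall fall, the largest named decreases lay mostly in 5'UTRs. The 5'UTR site of RABEPK had RML of 21.1 ± 3.4 (SD, n = 3) in siScram and 2.59 ± 0.51 in siPcif1, a log2 change of -2.81 ± 0.46 (SE; limma adjusted p = 1.1e-05). It was -2.33 after centring (limma adjusted p = 0.19). MAP2, a neuronal microtubule protein, had an intronic site with 28.1 ± 24 and 2.88 ± 1.4. CPSF2, a subunit of the cleavage and polyadenylation specificity factor, had a 5'UTR site with 46.1 ± 47 and 4.39 ± 0.59. GNL3 and NOL6, nucleolar proteins, had 5'UTR sites with log2 changes of -2.53 and -2.7. METTL3 had a 5'UTR site with 21.5 ± 8.4 and 5.68 ± 4.5 (limma adjusted p = 0.0043, or 0.24 after centring). MYCN, an oncogene amplified in a subset of neuroblastomas, had an intronic site at 0.491 ± 0.074 and 0.187 ± 0.06, a change of -0.53 that was -0.05 after centring. This was the lead site among 156 MYCN sites, and both means lay below the pseudocount of 0.502. The 5 sites called higher, named after their values were seen, were in SOX2-OT, H2AFX, ACE, FADS2 and TTC8, and 4 of them had a siScram RML under 0.7.

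For BE(2)-C with ATRA, limma called 0 sites, with 177 lower and 427 higher at an unadjusted p of 0.05. Centring each library on its median turned this balance to 899 lower and 361 higher. As deposited, limma called 12 sites lower and 3 higher without siScram replicate 1, and 9 and 6 with the replicate number as a block. The one-sided p-values of the authors' deposited table gave 277 lower and 952 higher, or 135 and 419 when doubled. The 5'UTR site of MAP2 had RML of 66.4 ± 38 (SD, n = 3) in siScram and 12.2 ± 4.4 in siPcif1 (limma adjusted p = 0.81). RET and PHOX2A, a receptor tyrosine kinase and an adrenergic transcription factor, had 5'UTR sites with log2 changes of -1.2 and -1.21, both at a limma adjusted p of 1. The lead site of MYCN among its 82 sites, in coding sequence, had a change of 0.58 (limma adjusted p = 1).

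The siPcif1 effect was compared between BE(2)-C with and without ATRA at 7800 shared sites. limma passed 7 interaction terms, all higher with ATRA, and 0 after each library was centred on its median (1302 higher and 10 lower at an unadjusted p of 0.05 as deposited, 228 and 857 after centring). Leaving out 1 library gave counts from 1 to 254, the highest without siScram replicate 1 of the cells without ATRA. Lowered sites did not overlap between contexts at an adjusted p of 0.05, since 2 of the contexts had 0. At an unadjusted p of 0.05, HEK293T and BE(2)-C without ATRA shared 278 lowered sites against 157 expected (Fisher's exact p = 8.3e-29), and after centring 75 against 24.7 (Fisher's exact p = 2.97e-19). These expected numbers do not allow for the larger fall of 5'UTR sites in both contexts. The test also treats sites of the same libraries as independent. Per gene, over non-DRACH 5'UTR sites, 64.7% of 1156 shared genes were lower in both contexts against 64.5% expected. Since 92.3% of all HEK293T genes had a negative change, this share had little room to differ from that expected. Pearson's r of the changes over these shared genes was 0.16. Given these limits, the overlap does not show that the same sites responded in both lines.

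Of the 14 gene lists fixed before the data were examined, 4 passed fry in HEK293T and 0 in BE(2)-C. Of 207 sites in nuclear genes of oxidative phosphorylation 167 had a negative change, with a median of -0.52 (fry adjusted p = 0.0161, against camera adjusted p = 0.329 with an estimated correlation). Adjusted over the list alone, 18 were lower, against 0 over all sites and 0 over the list alone after each library was centred on its median. The SDHA 5'UTR site had RML of 2.05 ± 0.37 (SD, n = 3) and 0.556 ± 0.096, and that of NDUFV2 11 ± 1.4 and 2.56 ± 0.75 (both limma adjusted p = 0.16). Proteasome genes had a negative change at 102 of 136 sites, with a median of -0.41 (fry adjusted p = 0.0432, against camera adjusted p = 0.473 with an estimated correlation), and 0 were lower adjusted over the list alone. Spliceosome, SR and hnRNP genes had a median of -0.15 over 217 sites (fry adjusted p = 0.0352, against camera adjusted p = 0.564 with an estimated correlation), with 4 lower and 1 higher adjusted over the list alone, or 1 and 0 after centring. Small nuclear and nucleolar RNAs had a median of -0.15 over 9 sites (fry adjusted p = 0.0352, or 0.0695 after centring, against camera adjusted p = 0.663 with an estimated correlation), with 2 lower adjusted over the list alone.

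In HEK293T the cleavage, polyadenylation and termination list had a median of -0.11 over 283 sites (fry adjusted p = 0.445). The m6A and m6Am machinery had 0.07 over 248 sites (fry adjusted p = 0.701) and replication histones -0.09 over 64 sites (fry adjusted p = 0.0969). Ribosomal proteins had -0.03, zinc finger genes -0.05 and the retinoic acid list -0.14 (fry adjusted p = 0.279, 0.712 and 0.544). Adrenergic neuroblastoma markers had -0.003 over 42 sites, mesenchymal markers 0.02 over 116 and neuronal differentiation genes 0.11 over 49 (fry adjusted p = 0.712, 0.985 and 0.701). Centring moved the median of all HEK293T sites from -0.08 to 0.05 and turned the medians of the cleavage, histone, ribosomal, zinc finger and adrenergic lists positive. After it the m6A and m6Am machinery had a median of 0.19 (fry adjusted p = 0.0272), and the mesenchymal, zinc finger and histone lists had 0.14, 0.07 and 0.03 (fry adjusted p = 0.0389 for each, with fry's direction down for histones). Camera with an estimated correlation gave adjusted p = 0.0722 for the machinery, 0.332 for the mesenchymal list, 0.105 for zinc finger genes and 0.332 for histones after centring. No BE(2)-C list passed fry, with adjusted p = 0.228 for each list without ATRA and 0.946 with ATRA. Without ATRA the adrenergic markers had a median of -0.34 over 831 sites and zinc finger genes -0.65 over 281 sites, of which 27 were lower, or 60 adjusted over the list alone. Cleavage and termination genes had -0.62 over 72 sites, with 5 lower, or 10 adjusted over the list alone. Camera with an estimated correlation gave adjusted p = 0.947 for these 3 lists. After centring, the medians were 0.14 for adrenergic markers, -0.17 for zinc finger genes and -0.14 for cleavage genes, with 0 sites lower in each list, also adjusted over the list alone. The machinery and neuronal differentiation lists then passed fry without ATRA, with medians of 0.13 and 0.20 (fry adjusted p = 0.015 and 0.0469), against camera adjusted p = 0.5 and 0.399 with an estimated correlation. The mitochondrial list matched no symbol of the tables, which hold 82, 30 and 76 sites on the mitochondrial chromosome for BE(2)-C without ATRA, with ATRA and HEK293T.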

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

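All tests of explanations in this part were chosen after the results were seen. The fall of 5'UTR RML relative to internal sites was larger in HEK293T than in BE(2)-C under the comparisons added later, although the planned comparison did not pass (exact permutation, adjusted p = 0.15). Against level-matched internal sites the shift differed by -0.56 from BE(2)-C without ATRA and by -0.40 from BE(2)-C with ATRA (exact permutation, adjusted p = 0.0075 for both), and by -0.16 between BE(2)-C with and without ATRA (adjusted p = 0.01). Against internal DRACH sites the differences were -0.54 and -0.53 for HEK293T (adjusted p = 0.015 and 0.0225). The relabeling reaches its smallest p only where the siScram libraries differ between contexts too. In the planned contrast siScram means were alike, at 1.09 in HEK293T, 1.14 without ATRA and 1.1 with ATRA. Level-matched siScram means were 0.355, 0.0698 and 0.128 in that order. The smaller p-values of the later comparisons therefore partly reflect the contrast used. Between BE(2)-C with and without ATRA the planned contrast differed by 0.03 (adjusted p = 0.785) and that against internal DRACH sites by -0.02 (adjusted p = 0.885), so that difference did not hold in 2 of the 3 comparisons. The depth of knockdown in each line was not measured here and stays open as a reason. The makeup of the tables stays open too, because each contrast used all sites of its own table and none was limited to shared sites. Internal sites had a DRACH motif at 60.3% in HEK293T, against 22.5% in BE(2)-C without ATRA and 24.8% with ATRA.

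A higher starting level of 5'UTR sites was examined as the whole cause of the HEK293T fall. Against internal sites of like mean level the shift was still -0.62, with a pooled SD of 0.031. Matching used the libraries of both groups, so starting levels were not equalised. The matched difference was 0.355 in siScram and -0.263 in siPcif1, so this comparison does not settle the question. Non-DRACH sites 51 to 100 nt from the gene start were at -0.618 relative to internal DRACH sites in siScram, yet changed by -0.535. For those sites, this argues against a higher starting level. Weaker enrichment in the siPcif1 libraries stays open. The median of internal DRACH sites changed by 0.0079 with a pooled SD of 0.089, so they did not fall along with 5'UTR sites. The scaling between libraries is not given, and a scaling to the bulk of sites could hide weaker enrichment. Loss of PCIF1-dependent methylation at transcript starts stays open. Non-DRACH sites changed by -0.0486 beyond 500 nt against -0.81 at 11 to 50 nt, but this largely restates the contrast of 5'UTR with internal sites and does not test that hypothesis. Off-target effects stay open too, because knockdown was not measured here and the labels do not say whether siPcif1 is a single siRNA or a pool.

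As the only cause of the fall at most sites in BE(2)-C without ATRA, 1 scale factor per library is argued against. Without a pseudocount the change of the highest of 10 bins of sites by level minus that of the lowest bin was -0.48, with a pooled SD of 0.12. The bins held sites of every class, so a scale factor joined to a further fall of 5'UTR sites was not tested. Lower internal m6A after siPcif1 and weaker enrichment both predict a fall of internal DRACH sites, which was -0.51 with a pooled SD of 0.26, and they cannot be told apart because enrichment was not measured apart from RML. The count of 848 changed sites came from the real split of the 6 libraries, and the highest of the other splits gave 52. With 10 splits, 1 of them as large, the share cannot go under 0.05.

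Within BE(2)-C with ATRA, siScram replicate 1 and siPcif1 replicate 3 were alike, with a correlation across sites of 0.908 and of 0.459 after removing group means. A shared difference in enrichment or background is consistent with their DRACH minus non-DRACH contrasts, the lower of which was 0.69 against at most 0.43 in the other 4 libraries. A swap of the 2 libraries is argued against by the level-matched 5'UTR contrast, where siPcif1 replicate 3 lay 0.128 below the lowest siScram library and siScram replicate 1 lay 0.136 above the highest siPcif1 library, with a pooled SD of 0.049. Against internal DRACH sites both gaps were 0.104 with a pooled SD of 0.088, and in the planned contrast siPcif1 replicate 3, at 1.02, lay within the siScram range, while siScram replicate 1, at 1.27, lay above all siPcif1 libraries. Another split of these libraries, with siScram replicates 1 and 3 and siPcif1 replicate 3 on one side, gave 4767 sites against 0 for the real split, a count that all 10 splits reached, which points to a structure of the samples other than the siRNA.

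The siPcif1 change differed between BE(2)-C with and without ATRA at 7 sites. Of 100 splits 3 gave as many, and 1 gave 3936, so the libraries hold a structure larger than this effect. In HEK293T all 10 splits gave 0 sites, as did the real one. For genes by start-site RML, the real split gave 217 and the others at most 0, which 10 splits cannot place under 0.05 (1 as large). For BE(2)-C without and with ATRA all 10 splits gave 0 genes.

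Sites outside 5'UTR, coding and 3'UTR sequence were not part of the contrast of 5'UTR with internal sites. In HEK293T the 949 of them in the BCA context changed by -0.44 relative to internal DRACH sites, against 0.01 for the 2428 with a DRACH motif (exact permutation p = 0.1 and p = 0.5). The BCA sites changed by -0.14 in BE(2)-C without ATRA over 266 sites and by -0.02 with ATRA over 295 sites (exact permutation p = 0.1 and p = 0.9).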

How the results depend on the processing

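Comparison sites other than the 50 nt window and DRACH alone, centring on internal DRACH sites, values without a pseudocount, overlaps after centring, doubled p-values and every setting of the gene-level test were added after the data had been seen. The input correction was not run, because input libraries have no column of their own, and the filter at 0 removed no site. The cause was not tested for any change below unless given.

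The HEK293T 5'UTR shift kept its direction under every setting run, from -0.291 with DRACH alone to -0.799 without a pseudocount. It was -0.789 within 50 nt of the gene start, -0.654 by means, -0.644 at sites above the median siScram level, -0.477 with the median as pseudocount and -0.618 against level-matched sites. Leaving out 1 library gave -0.697 to -0.765. In BE(2)-C without ATRA the shift was -0.233 by means, -0.183 at sites above the median siScram level, -0.0576 against level-matched sites and -0.229 against internal DRACH sites. With DRACH alone as the class it was 0.0525 without ATRA and 0.0309 with ATRA, where most non-DRACH sites are internal. Leaving out 1 library gave -0.245 to -0.295 without ATRA and -0.16 to -0.322 with ATRA.

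Counts of lowered and raised sites in BE(2)-C without ATRA were 0 and 0 with each library centred on its median or on internal DRACH sites, 1 and 0 without trend, 1 and 0 with the deposited one-sided p-values after adjustment and 0 and 0 with these doubled. Only 1 site was raised among sites above the median siScram level. Leaving out 1 library gave 40 to 12188 lowered and 2 to 22 raised sites. With ATRA it gave 0 to 12 lowered and 0 to 13 raised, and in HEK293T 0 and 0. The deposited p-values gave 2 lowered sites in HEK293T, or 1 when doubled. Of the 30 named sites of BE(2)-C without ATRA, 26 passed as deposited and 0 after centring. STMN2 turned from -0.366 to 0.116 on centring and 0.145 when centred on internal DRACH sites.

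Genes with lower start-site RML in HEK293T numbered 343 with all internal sites as reference, 133 with the median as pseudocount and 0 without trend. Leaving out 1 library gave 0 to 2 genes there, with fewer samples, 0 to 5 in BE(2)-C with ATRA and 0 to 0 without ATRA. Raised genes numbered 0 to 1 without ATRA. Gene lists past fry numbered 2 on centring and 2 by start-site genes without ATRA, 3 by start-site genes with ATRA, and 7 on centring, 7 with 1 site per gene and 9 by start-site genes in HEK293T. None of these lists passed camera with an estimated correlation, where the smallest adjusted p was 0.056, for oxidative phosphorylation on centring in HEK293T. Shared lowered sites at an unadjusted p of 0.05 numbered 278 for HEK293T and BE(2)-C without ATRA, 40 for HEK293T and BE(2)-C with ATRA and 28 for the BE(2)-C contexts, and 75, 88 and 24 after centring. Sites that differed by ATRA numbered 0 on centring and 1 to 254 without 1 library.

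The labels do not say whether replicate numbers pair the samples, and the values leave this open. Deviations of same-numbered libraries correlated by 0.116, 0.0048 and 0.00858 in BE(2)-C without ATRA and by -0.309, 0.062 and -0.258 with ATRA. In HEK293T they correlated by 0.0202, 0.0148 and 0.00429, against at most 0.00296 for differently numbered libraries of the 2 groups. With the replicate block, 2935 sites were lowered and 8 raised without ATRA, 9 and 6 with ATRA and 0 in HEK293T, 17 sites differed by ATRA, and the count of HEK293T genes by start site was 0. Unknown depth leaves the precision of low ratios open.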

Other observations

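The list tests and counts in this part were chosen after the data had been seen. When HEK293T genes were tested by their start sites, 9 gene lists passed fry, and the median over all 5069 genes was -0.74. Among them, the cleavage and termination list fell with a median of -0.65 over 23 genes (fry adjusted p = 0.00037) and replication histones with -1.09 over 21 genes (fry adjusted p = 0.000801). Ribosomal proteins fell with -0.39 over 60 genes (fry adjusted p = 0.000801), so ribosomal and cleavage genes had medians nearer to 0 than all genes. Against the other genes, camera with an estimated correlation gave adjusted p = 0.897 for all of these lists. Sites of MYCN numbered 156 without ATRA and 82 with ATRA, those of CHGA 245 and 77, and those of NCL 139 and 29. Other genes had more or about as many with ATRA, with 116 and 147 sites in SCG2, 145 and 149 in CHGB, 86 and 84 in HAND2 and 0 and 13 in CYP26A1. Such numbers depend on how sites were called.

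The oxidative phosphorylation and proteasome lists had the lowest medians over all sites in HEK293T, and a candidate explanation is their makeup. With 1 site per gene, replication histones at -0.998, the spliceosome list at -0.861 and neuronal differentiation genes at -0.782 lay below them, at -0.715 and -0.781. Of their sites, 86% and 64.7% lay in 5'UTRs, against 21.7% of all sites. Their internal sites had median changes of 0.0374 and -0.00645. This is consistent with lists that differ by the share of 5'UTR sites they hold.

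Changes of start-site RML per gene were weakly related across contexts. Pearson's r across genes, which are not independent replicates, was 0.16 between HEK293T and BE(2)-C without ATRA over 1156 genes, 0.083 with ATRA over 1110 genes and 0.052 between the BE(2)-C contexts over 893 genes.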
